A study of Mus musculus with 3 samples.

How the data were processed

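RNA was measured on 2-colour Agilent mouse oligonucleotide arrays. The samples were 3 separate cultures of mouse ovarian surface epithelium, the cell layer that covers the ovary. Per the labels, each culture was divided into a part kept epithelial in 2.5% fetal bovine serum and a part held for 1 week in 15% serum, which turned it mesenchymal. Cells were collected at 80% confluence, and amplified RNA was made from 4 µg of total RNA per labelling. Both RNAs of a culture were hybridised together on 2 arrays with the dyes exchanged, giving 6 arrays. The cultures are biological replicates, and the 2 arrays of a culture were treated as 1 replicate (n = 3).

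The deposited scanner files are output of Agilent's Feature Extraction software. Per the file headers, the intensities used here are spot means and local backgrounds as scanned, in linear units, and the processed intensities were background-subtracted and lowess dye-normalised within the array by that software. The log10 ratios of Cy5 over Cy3 were computed by that software from the processed intensities, as deposited. The authors' deposited value table holds log10 ratios, and from the values each column equals the mesenchymal over epithelial difference of the 2 arrays' log10 ratios divided by 2, with a correlation of 1 over probes. Its medians are 0.00555, -0.0101 and -0.00233 for cultures 1, 2 and 3, so its scale and centring are known, and its direction rests, like that of every ratio here, on the dye orientation of the arrays. The submitters' processing notes list limma, with no version or settings. The labels list both dyes for both RNAs, and which array has which orientation was taken from the dye statement in the names of the deposited arrays.

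From the mean signal and local background, intensities were corrected with normexp (offset 50) and log2 ratios were normalised by loess within each array in limma 3.58.1 under R 4.3.3, with control spots at weight 0. Each array was turned to mesenchymal over epithelial, and the 2 arrays of a culture were averaged, so that a probe's dye effect cancels. Outlier-flagged spots were left out, and a culture then had a value only if both of its arrays had one. Saturated spots were kept, and saturation of the brighter RNA makes a ratio smaller. Control spots were left out, which left 20371 probes, each present once. A probe was kept if the scanner's well-above-background flag was set for the same RNA on at least 4 of the 6 arrays, which removed 43 probes. This filter is weak, since 18.5% to 81.5% of the negative control spots carried the flag. For each gene the probe with the highest mean brightness was used. Probes without a gene name were kept as features of their own. At least 2 cultures had to be measured, a rule set, like that on both arrays, after the data were examined. Of the 17582 features tested, 9957 had a name and 2105 rested on 2 cultures.

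Names came from the gene IDs of the array files matched to a RefSeq table of assembly GRCm38.p6 (9946 probes), from a current symbol (95), from a synonym held by only 1 gene (1335) or from the file's own name (1256), and 7739 probes stayed unnamed. Of 5306 named probes that also had a matched accession, the accession of 39 gave another gene than the name used. On 1 array, culture 3 with mesenchymal RNA in Cy3, another version of the annotation was used, the scanner software subtracted a constant background, and 1639 probes were outlier-flagged against 61 to 467 on the others. Probes were therefore aligned by their place on the array.

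Each log2 ratio was tested against 0 with limma (lmFit and eBayes), with Benjamini-Hochberg adjusted p under 0.05 over all features. The 43 gene lists, fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01 on the 15477 features measured in all 3 cultures, adjusted over the lists. Of these lists, 42 had at least 3 measured members. Camera was also run with an estimated correlation. Its test then has only the 2 residual degrees of freedom of 3 cultures, so it can call little. The dye effect was tested with limma like the log2 ratios, on the sum of a culture's unturned log2 ratios divided by 2. A gene that was saturated for an RNA on all 6 arrays has only a bound, given as "at least N-fold" from separate channels after loess and Aquantile scaling.

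Genes were named by a rule set in advance. Of genes past the threshold with the same sign on all 6 arrays, the 10 with the largest positive and the 10 with the largest negative mean log2 ratio were taken, leaving out unnamed, RIKEN, predicted and expressed-sequence names. Up to 4 called members with the largest change were taken from each list, or the 2 brightest members where fewer than 2 were called. Also named whatever their values were Cdh1, Cdh2, Vim, Fn1, Acta2, Krt8, Krt18, Krt19, Snai1, Snai2, Twist1, Zeb1, Zeb2, Wt1 and Mki67. Some genes that this rule takes are not reported here, and no others were put in their place.

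The steps were tested on simulated arrays with the dye effects and spread of the 20371 real probes. Of the simulated changes of this comparison, 13.4% were recovered at a log2 change of 0.5, 82.1% at 1 and 98.5% at 2, and 3 of 135 calls were of unchanged probes. Apart from a shifted list, only 200 probes were changed, with independent noise and no missing values, whereas 11.9% of real features were called. These rates therefore need not hold for the real data. Alternatives were no background subtraction, an offset of 16, the scanner's processed signals, median centring, Aquantile scaling, the authors' value table, other filters and probe rules, other thresholds, a fit over 6 arrays with a dye term, a fit with no replicate block, each dye orientation on its own, and leaving out each culture. Filtering at the 95th percentile of negative controls, leaving out saturated probes and keeping outlier-flagged spots were added after seeing the data. The median signal over local background was 11.3 to 16.6 in Cy5 and 20.0 to 58.2 in Cy3, and the number of arrays limits the precision.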

Results

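Gene expression was compared between mouse ovarian surface epithelial cells kept epithelial in 2.5% serum and cells of the same cultures made mesenchymal by 1 week in 15% serum. There were 3 separate cultures, each measured on 2 arrays with exchanged dyes. Values are log2 ratios of mesenchymal over epithelial RNA, given as mean ± SD over cultures (n = 3 unless stated), and adjusted p is from limma. The comparison asks how the transcriptome of these cells differs before and after an epithelial to mesenchymal transition. Serum concentration and phenotype changed together in every culture, so no difference given below can be assigned to 1 of them apart from the other.

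In mesenchymal cells, Krt14, a keratin of epithelial cells, fell by 3.22 ± 0.35 on the log2 scale (adjusted p = 0.000173), and the membrane glycoprotein gene Gpm6a fell by 2.98 ± 0.22. The collagen gene Col1a2 had a log2 ratio of -3.18 ± 0.12 (adjusted p = 8.22e-05). Igf2, an imprinted growth factor gene, rose by 3.32 ± 0.22 (adjusted p = 8.33e-05), and Ank, which encodes a pyrophosphate transporter, rose by 3.69 ± 0.50. In all, 2088 of 17582 features changed, 1048 higher and 1040 lower in mesenchymal cells, and 317 of them changed at least 2-fold. The sign was the same on all 6 arrays for 1271 of the 2088.

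Others among the 10 strongest rises were Ackr3, an atypical chemokine receptor gene (2.84 ± 0.41), Prl2c2 (2.59 ± 0.31), F3, the gene of tissue factor (2.51 ± 0.19), and Pdgfrb, a receptor for platelet-derived growth factor (2.50 ± 0.17). Selenop, a selenium transport protein gene, rose by 2.39 ± 0.11, Spp1, which encodes osteopontin, by 2.22 ± 0.24, Masp1 by 2.18 ± 0.10 and Chst1 by 2.11 ± 0.38. Others among the 10 strongest falls were Cyria (-2.68 ± 0.14), Dmd, the dystrophin gene (-2.44 ± 0.25), Megf6 (-2.44 ± 0.27) and Cth, an enzyme of cysteine synthesis (-2.39 ± 0.06). Mycn, a MYC family transcription factor gene, had a log2 ratio of -2.33 ± 0.27, the matrix proteoglycan gene Fmod -2.25 ± 0.03 and Trib3, a stress-induced pseudokinase gene, -2.21 ± 0.07. Adjusted p for these 20 genes was at most 0.000586. Another, dimmer probe gave -0.021 for Col1a2 and -0.061 for Igf2, so these changes rest on 1 of 2 probes. The Col1a2 probe was saturated for epithelial RNA on 4 of 6 arrays, and its call ended when saturated probes were left out.

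**Figure D1:**
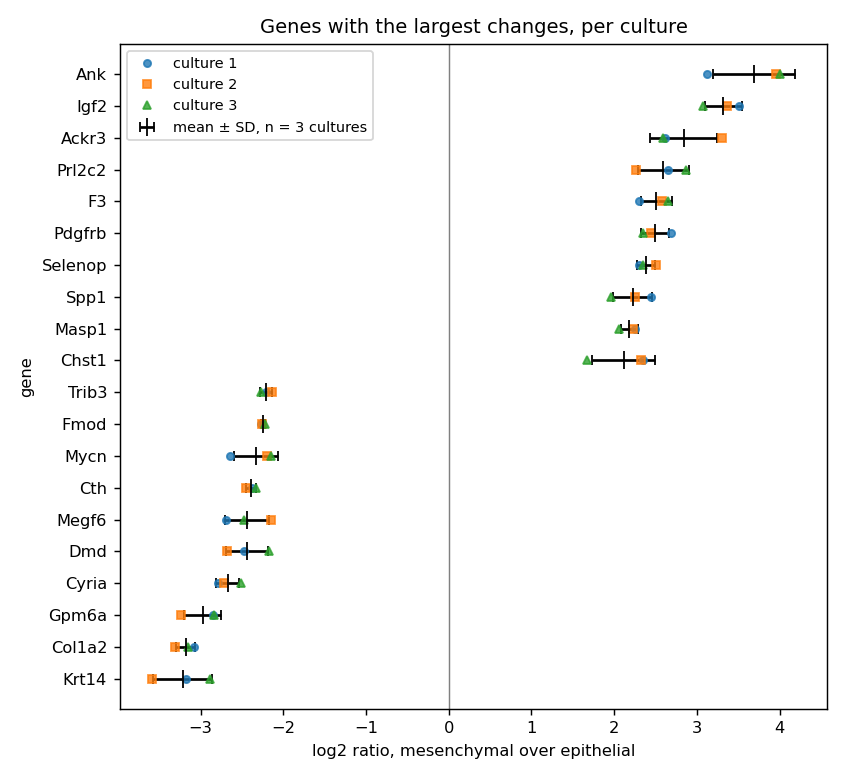
Log2 ratio of mesenchymal over epithelial RNA (x axis) for the 10 genes with the largest rise and the 10 with the largest fall (y axis). Symbols are the 3 cultures and bars are mean ± SD. Genes were taken only if all 6 arrays had the same sign, so every culture lies on the same side of 0 by selection. Means run from Ank at 3.69 to Krt14 at -3.22. Col1a2 was saturated for epithelial RNA on 4 of 6 arrays, so its place in the order is not settled.

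The number of changed genes depended on each culture. It was 5116 without culture 1, 1148 without culture 2 and 826 without culture 3. Across genes, which are not independent replicates, the log2 ratios of cultures 2 and 3 correlated at 0.89, those of cultures 1 and 2 at 0.61 and those of cultures 1 and 3 at 0.65.

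Markers of the ovarian surface epithelium and mesothelium fell as a list (camera adjusted p = 0.000538; adjusted p = 0.324 with an estimated correlation). Of 19 measured members, 10 were lower, 3 higher and 6 not past the threshold; adjusted over the list alone, 12 were lower and 3 higher. Besides Gpm6a, mesothelin (Msln) fell by 2.07 ± 0.27 and the transcription factor gene Wt1 by 0.89 ± 0.10. The stem cell antigen gene Ly6a went the other way, at 1.80 ± 0.42. Krt7 was at least 3.56-fold lower, since it was saturated in epithelial RNA on all 6 arrays; another, dimmer Krt7 probe gave -0.37. Keratins fell as a list (camera adjusted p = 0.000525; adjusted p = 0.324 with an estimated correlation), with 4 of 6 lower and 0 higher; adjusted over the list alone, 5 were lower and 1 higher. Krt19 had a log2 ratio of -0.91 ± 0.09 and Krt8 of -0.32 ± 0.06, while Krt18, at -0.46 ± 0.42, did not pass (adjusted p = 0.129) but was called without culture 1 (-0.70). The Krt8 call was lost without culture 2, without culture 3 and without saturated probes, its probe being saturated for mesenchymal RNA on 3 arrays and for epithelial RNA on the other 3.

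Genes of epithelial junctions and identity were lower as a list. Of 32 measured, 5 were lower and 27 not past the threshold, with the same 5 adjusted over the list alone (camera adjusted p = 0.0120; adjusted p = 0.464 with an estimated correlation). The protease inhibitor gene Spint2 fell by 2.04 ± 0.17. Pkp2, a desmosome gene, fell by 0.74 ± 0.22 and Cgn by 0.43 ± 0.12, a call lost without culture 2 or culture 3. Cdh1, the gene of E-cadherin, was at 0.23 ± 0.06 and did not pass (adjusted p = 0.0914), but it was called without culture 1 (0.21). The list's camera call was lost without culture 3 and with the authors' value table, and outlier-flagged spots, when kept, also ended it.

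Mesenchymal marker genes were lower as a list (camera adjusted p = 0.00149; adjusted p = 0.324 with an estimated correlation). Of 26 measured, 10 were lower, 2 higher and 14 not past the threshold; adjusted over the list alone, 12 were lower and 2 higher. The basement membrane gene Nid2 fell by 2.04 ± 0.18, the cadherin gene Cdh11 by 1.84 ± 0.14 and Acta2, the gene of smooth muscle actin, by 1.19 ± 0.05, whereas Pdgfrb rose. Another, dimmer Cdh11 probe gave 0.11. Vim and Fn1, the genes of vimentin and fibronectin, were saturated in both RNAs on nearly every array, so no fold is given for them. Cdh2 was at 0.31 ± 0.27 (adjusted p = 0.154) and was called without culture 1 (0.47). The list's call was lost when saturated probes were left out (camera adjusted p = 0.0648).

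Of the transcription factors linked to the transition, Snai1 rose by 0.65 ± 0.07 (adjusted p = 0.00307), Hmga2, a chromatin protein gene, by 1.90 ± 0.37 and Id2, a dominant-negative helix-loop-helix gene, by 1.04 ± 0.14. Snai2 was higher by 0.28 ± 0.02 (adjusted p = 0.0489), a call lost without culture 2 or culture 3, with median centring and with the authors' value table. Tbx3 fell by 0.38 ± 0.03, a call also lost without culture 2 or culture 3. Twist1 was at 0.010 ± 0.14, Zeb1 at -0.30 ± 0.21 and Zeb2 at 0.091 ± 0.23, none past the threshold; Zeb1 was called without culture 1 (-0.41). In the list, 4 of 16 were higher, 1 lower and 11 not past the threshold, with the same counts adjusted over the list alone. Camera, which compares a list with the other genes, did not call the list (adjusted p = 0.242). Fry, which compares it with no change, called it higher (adjusted p = 0.0338).

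**Figure D2:**
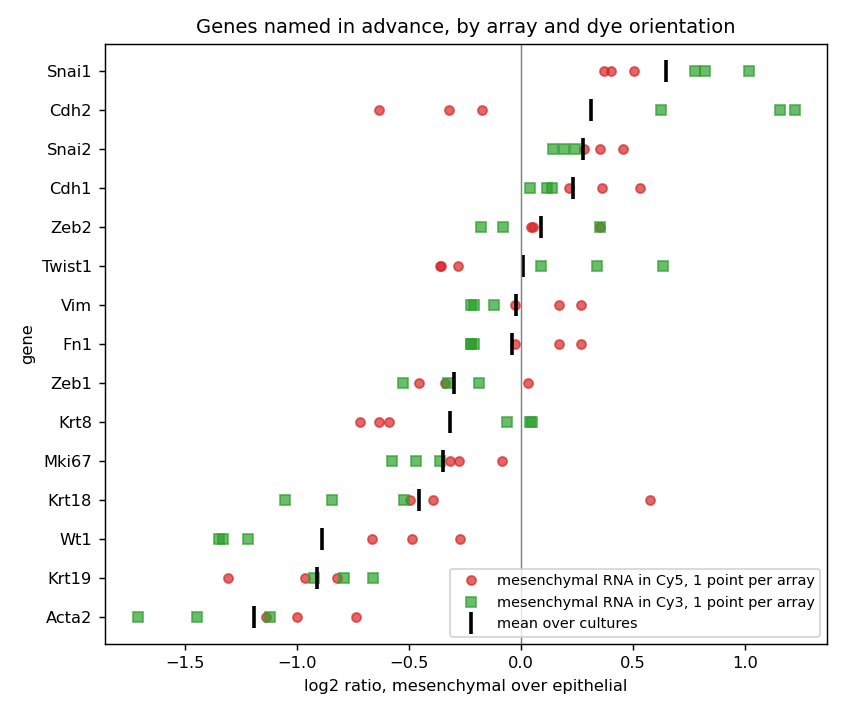
Log2 ratio of mesenchymal over epithelial RNA (x axis) on each of the 6 arrays for the 15 genes named in advance (y axis), by the dye that held mesenchymal RNA. The bar is the mean over cultures; for Cdh2 and Twist1 the arrays of the 2 orientations lie on opposite sides of 0, while Acta2 and Wt1 are below 0 and Snai1 above 0 on all 6.

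Of the matrix lists, those of basement membrane and of collagens were called lower. Basement membrane genes had 7 of 14 members lower and 0 higher, 10 lower adjusted over the list alone (camera adjusted p = 3.14e-05; adjusted p = 0.324 with an estimated correlation). The type IV collagen genes Col4a6, Col4a1 and Col4a2 fell by 1.95 ± 0.27, 1.42 ± 0.08 and 1.39 ± 0.33. The Col4a1 and Col4a2 probes were saturated for epithelial RNA on 2 and 3 of 6 arrays, which makes their measured falls smaller. Of 11 fibrillar and other collagens, 5 were lower and 0 higher, and 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.94e-05; adjusted p = 0.324 with an estimated correlation). Col5a2 fell by 1.63 ± 0.22 and Col6a1 by 1.16 ± 0.19. Col5a2 was above 0 on 1 array and below 0 on 5, and its dye effect, at -1.46, was nearly as large as its change. Genes of other matrix glycoproteins and enzymes went both ways, with 9 of 26 lower and 4 higher, or 11 and 4 adjusted over the list alone (camera adjusted p = 0.142). Among these, the crosslinking enzyme gene Lox fell by 1.68 ± 0.25, and Tgfbi and Spp1 rose by 1.69 ± 0.47 and 2.22 ± 0.24.

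Targets of the transcriptional regulators SRF and YAP, many of which build the contractile cytoskeleton, were lower as a list (camera adjusted p = 0.00127; adjusted p = 0.324 with an estimated correlation). Of 28 measured, 13 were lower and 4 higher, or 14 and 5 adjusted over the list alone. Ccn2 fell by 1.72 ± 0.24 and the focal adhesion gene Zyx by 1.30 ± 0.25, whereas F3 rose. Another, dimmer Ccn2 probe gave 0.10. Ccn2, Zyx and Acta2 were saturated for epithelial RNA on 4 or 5 of 6 arrays, and without saturated probes the list's camera adjusted p was 0.135.

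TGF-beta family ligands, receptors and antagonists were lower as a list (camera adjusted p = 0.0117; adjusted p = 0.404 with an estimated correlation), with 9 of 27 lower and 3 higher, or 9 and 5 adjusted over the list alone. Tgfb2 fell by 2.14 ± 0.11 and the receptor gene Tgfbr2 by 1.30 ± 0.10, while the antagonist gene Grem1 was higher by 1.01 ± 0.64, or 0.64 without culture 1. Another, dimmer Tgfbr2 probe gave 0.072. The calls of the list and of Grem1 were lost without culture 3. TGF-beta response genes had 4 of 15 lower and 3 higher, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.212); Pmepa1 fell by 1.05 ± 0.11.

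Hypoxia response genes were lower as a list (camera adjusted p = 3.94e-05; adjusted p = 0.324 with an estimated correlation). Of 18 measured, 8 were lower and 1 higher, or 9 and 2 adjusted over the list alone. Ddit4, an inhibitor of mTOR signalling, fell by 1.74 ± 0.11, the oxidase gene Ero1a by 1.62 ± 0.06 and Ndrg1 by 1.36 ± 0.13. The unfolded protein response list was lower (camera adjusted p = 0.00322; adjusted p = 0.324 with an estimated correlation), with 5 of 18 lower and 0 higher, or 8 lower adjusted over the list alone. Its strongest members were Trib3 and the asparagine synthetase gene Asns (-0.76 ± 0.25), both known targets of the amino acid stress factor ATF4. The Asns call was lost without culture 3. Asns was above 0 on 3 arrays and below 0 on 3, and its dye effect, at -1.58, was larger than its change.

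Both lipid synthesis lists were called lower by camera at its preset correlation, though most of their members did not pass the threshold. Of 19 cholesterol genes, 7 were lower and 1 higher, with the same counts adjusted over the list alone (camera adjusted p = 0.00242; adjusted p = 0.324 with an estimated correlation). Srebf2, which encodes a regulator of this pathway, fell by 0.58 ± 0.06, while Ebp rose by 0.74 ± 0.31. The Srebf2 call was lost without culture 3. Of 14 fatty acid synthesis genes, 3 were lower and 1 higher, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0250; adjusted p = 0.381 with an estimated correlation). The desaturase gene Fads2 fell by 0.82 ± 0.07. The fatty acid list's call was lost without any 1 culture and without saturated probes. Oxidative phosphorylation was the only list called higher (camera adjusted p = 0.00475; adjusted p = 0.405 with an estimated correlation). Of its 31 members 3 were higher and 0 lower, or 9 higher adjusted over the list alone, led by Cox6b1 at 0.59 ± 0.17. Cox6b1 was above 0 on 3 arrays and below 0 on 3, and its dye effect, at -1.13, was larger than its change. The list's call was lost without culture 1, with median centring and with fry.

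Interferon response genes were lower as a list, with 6 of 20 lower and 0 higher, or 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00498; adjusted p = 0.324 with an estimated correlation). Bst2 fell by 1.76 ± 0.29 and the immunoproteasome gene Psmb8 by 1.49 ± 0.31 (n = 2). Neural crest and nervous system genes had 8 of 20 lower and 2 higher, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.0117; adjusted p = 0.331 with an estimated correlation). The semaphorin receptor gene Nrp1 rose by 1.89 ± 0.02 and Plxnb1 fell by 0.72 ± 0.06. This list's call was lost without culture 1 and with fry.

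**Figure D3:**
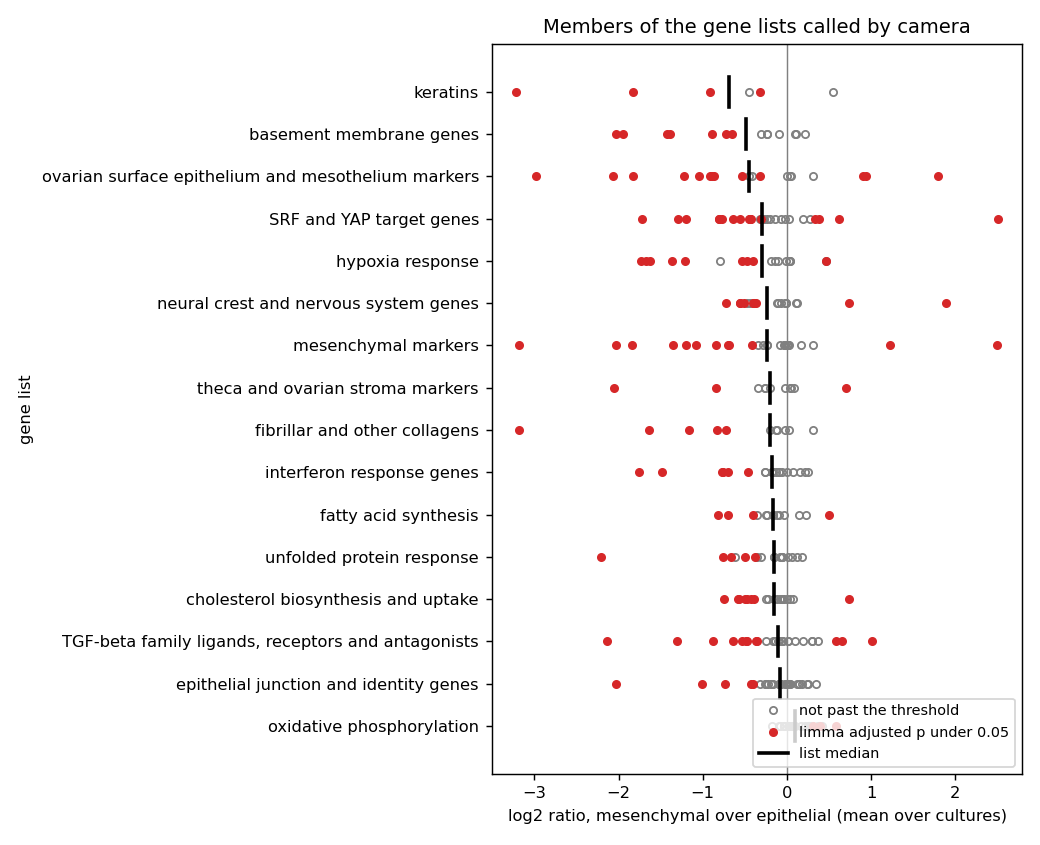
Mean log2 ratio of mesenchymal over epithelial RNA (x axis) of each measured member of the 16 gene lists called by camera (y axis). Filled points passed limma's threshold and the black bar is the list median, from -0.68 for keratins to 0.10 for oxidative phosphorylation, which is the only list above 0.

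Markers of proliferation and of other cell types were also measured. Mki67, a marker of dividing cells, fell by 0.35 ± 0.08 (adjusted p = 0.0284), a call lost without culture 2 or culture 3; another, dimmer probe gave 0.083. Of 37 genes of the start of the cell cycle and replication, 7 were higher and 4 lower, or 7 and 6 adjusted over the list alone (camera adjusted p = 0.158), and of 38 genes of its later phases 6 were higher and 2 lower, or 8 and 3 (camera adjusted p = 0.216). Theca and ovarian stroma markers were lower as a list (camera adjusted p = 0.0386; adjusted p = 0.404 with an estimated correlation), with 2 of 11 lower and 1 higher, or 5 and 1 adjusted over the list alone. Ogn fell by 2.05 ± 0.19, Pdgfra fell by 0.84 ± 0.27 and Ptch1 rose by 0.71 ± 0.30. Pdgfra was above 0 on 2 arrays and below 0 on 4, and Ptch1 above 0 on 4 and below 0 on 2. Their dye effects, at -0.94 and -0.82, were larger than their changes. The calls of the list and of Ptch1 were lost without culture 3, and that of the list also with the authors' value table and with outlier-flagged spots kept. Of 13 smooth muscle and pericyte markers, 3 were lower and 1 higher, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.107).

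The dye effect was larger than the change between the cells. It passed the threshold for 10035 features, and its SD over features was 0.46, against 0.31 for the log2 ratio between cells. Turned to mesenchymal over epithelial, arrays of the same orientation correlated across genes at 0.81 to 0.93 and arrays of opposite orientation at -0.50 to -0.10, so that a log2 ratio from only 1 orientation would be moved by dye. Of the 42 lists tested, camera called 16 at its preset correlation and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. For collagens the estimated correlation, -0.096, was below the preset 0.01, yet the unadjusted camera p rose from 2.82e-06 to 0.0397. For keratins it was higher, at 0.101. With 2 residual degrees of freedom few lists can pass, so the 0 calls do not show that correlation between genes undoes the list calls. Fry tests whether a list's genes move 1 way on balance, against no change, whereas camera tests them against the other genes. The 2 tests ask different questions, so their calls can differ. Fry called 23 lists, of which 4 were higher and 19 lower. Those higher were the transition factors (fry adjusted p = 0.0338), growth factors (0.0338), NRF2 genes (0.0135) and ciliated markers (0.0376). Fry also called lower some lists that camera did not. They were TGF-beta response (0.0376), other matrix (0.0376), glycolysis (0.0244), granulosa (0.0176) and chemokines (0.04995).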

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

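The filter at the negative controls, the removal of saturated probes and the keeping of outlier-flagged spots were chosen after seeing the data. The 2088 changed genes ranged from 1477 to 2496 over the alternatives in background, normalisation, filter, probe rule and variance model and the fit over 6 arrays; with trend and robust variance 690 were higher. Aquantile scaling leaves the ratios as they are, and the filter on dim probes removes few probes. A fit with no replicate block called 244 (112 higher, 132 lower). Only arrays with epithelial RNA in Cy3 called 7047 (3206 higher, 3841 lower), and only those with it in Cy5 5882 (3440 and 2442), of which dye effects are part by construction. At adjusted p under 0.01 the count was 933 (444 and 489), and at 2-fold or more 317 (126 and 191). Leaving out a culture gave 826 to 5116 changed genes, 397 to 2838 higher and 429 to 2278 lower. Lists called numbered 16, but 6 and 3 with only epithelial Cy3 or Cy5 arrays, 0 with an estimated correlation, and 12 to 17 without a culture. The fit over 6 arrays with a dye term called 15, and that with no replicate block called 14. The dye effect numbered 5673 to 9619 without a culture. Slide as a random block was not run, since each slide held 1 array.

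With only arrays with epithelial RNA in Cy3, the sign turned for Cdh2 (-0.38), Twist1 (-0.33), Btg2 (0.061), Acsl3 (-0.40), Dgat2 (0.042), Slc2a1 (-1.29), Cox6b1 (-0.54), Rpsa (-0.29), Cat (-0.49), Ptch1 (-0.12) and Slc4a1 (0.27), and for the epithelial junction list (median 0.077). With only those in Cy5, it turned for Krt8 (0.0092), Adamts5 (0.70), Inhba (0.75), Rfng (-0.60), Gpam (0.48), Asns (0.82), Scarb1 (0.12), Gja1 (0.46) and Pdgfra (0.11). Without saturated probes, other probes of Ccn2 (0.10) and Rpsa (-0.11) turned the sign. Fry called the growth factor list, of median -0.050, higher where camera's uncalled direction was lower. Of 3273 other values of 157 named genes, 3021 kept their side of the threshold, 216 lost it, 14 gained it and 22 turned, and 18 of the 3021 were uncalled values that crossed 0. Of 924 other values of the 42 lists, 843 kept their side, 60 lost it, 19 gained it and 2 turned, and 34 of the 843 were uncalled values that crossed 0. Apart from construction, the cause was not tested. Signal over background was 11.3 or more at the median, which says little of the dim probes. With the filter at the negative controls, 2081 of the 2088 calls were kept, so probes at that level limit few calls. Saturation limits bright ones.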

Other observations

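Growth factor genes moved both ways. Of 35 ligands and receptors of the EGF, FGF, HGF, PDGF and IGF families, 7 were higher and 10 lower, or 8 and 10 adjusted over the list alone (camera adjusted p = 0.883, median -0.050, mean 0.054). Igf2 and Pdgfrb rose, while Pdgfa, a ligand of the platelet-derived growth factor receptors, fell by 1.79 ± 0.04. Immediate early and feedback genes had 7 of 24 higher and 2 lower, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.212), with Egr1 at 0.87 ± 0.37, a call lost without culture 3, and Fosl1 at 0.86 ± 0.05. Imprinted genes had 3 of 17 higher and 5 lower, or 3 and 6 (camera adjusted p = 0.430), with Peg3 at 1.45 ± 0.07, Mest at -1.27 ± 0.39 and Meg3 at -1.25 ± 0.14. Another, dimmer probe gave 0.12 for Peg3, and of the other Meg3 probes the brightest gave -1.28 and the next 0.076. Progenitor genes had 4 of 16 higher and 2 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.985), among them Ly6a, which rose, and Mycn, which fell. Wnt genes had 2 of 21 higher and 2 lower, or 3 and 2 (camera adjusted p = 0.883), with Wnt4 at 1.10 ± 0.12 and Wnt5b at -1.35 ± 0.18. Of 20 NRF2 and glutathione genes, 5 were higher and 1 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.201), led by Gpx4 at 0.77 ± 0.03.

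Proteases and inhibitors had 2 of 17 higher and 5 lower (camera adjusted p = 0.407), with Plat at 1.46 ± 0.22 and -0.094 on a dimmer probe, and integrins 0 of 15 higher and 2 lower (0.708). Kinase inhibitors and p53 targets had 1 of 22 higher and 4 lower (0.241), with Zmat3 at -1.61 ± 0.23 and -0.37 on a dimmer probe, glycolysis 2 of 20 higher and 4 lower (0.0898), and the Notch pathway 0 of 13 higher and 1 lower (0.407). Antigen presentation and complement had 3 of 18 higher and 4 lower (0.883), with Clu at 2.06 ± 0.28 and H2-D1 at -1.42 ± 0.10 and 0.025 on a dimmer probe, and chemokines and cytokines 0 of 16 higher and 4 lower (0.708). Steroid genes had 1 of 19 higher and 1 lower (0.430), and ribosomal protein genes, 17 of 30 of them saturated in both RNAs, 2 higher and 0 lower (0.907). Granulosa markers had 0 of 14 higher and 3 lower (0.0760), endothelial markers 1 of 9 higher (0.883), leukocyte markers 1 of 13 higher (0.883), ciliated and oviductal markers 2 of 9 higher (0.212), and oocyte markers 1 of 15 higher and 1 lower (0.883), the higher being Ddx4 at 1.66 ± 0.17. Of the erythroid and platelet markers 2 were measured, too few for camera, and Ppbp was at 0.73 ± 0.15. Adjusted over the list alone, the counts higher and lower were 2 and 6 for proteases, 2 and 6 for kinase inhibitors, 2 and 6 for glycolysis and 1 and 0 for ribosomal proteins, and in the other lists of this paragraph they were as given. The median, the mean and camera's direction differed in sign for the growth factor, imprinted, progenitor, integrin, chemokine, ribosomal, endothelial, leukocyte and oocyte lists, none of them called by camera.

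In the weighing that follows, the tests of exchanged RNAs, of dye bias with its measure of spread, of other cell types and of serum were chosen after results were seen. The lists of collagens, basement membrane, mesenchymal markers and SRF and YAP targets were called lower at camera's preset correlation, though not with an estimated one. The calls of the mesenchymal list and of the SRF and YAP list were lost without saturated probes. These lists are not separate results, since the mesenchymal list shares Col1a2 with the collagens, Nid2 with basement membrane and Acta2 with the SRF and YAP targets. The lists of other matrix proteins, proteases, integrins and smooth muscle were not called by camera. An exchange of the 2 RNAs on every array cannot be settled by these data. The keratins go against it, with a median of -0.68, 4 lower and 0 higher. So do the markers of ovarian surface epithelium and mesothelium, which share keratins (10 lower, 3 higher), and the epithelial junction genes (5 lower, 0 higher). Of the transition factors 4 were higher and 1 lower, in a list that camera did not call. The mesenchymal markers go with an exchange, with 10 lower and 2 higher, but they are part of the pattern to be explained. The dye orientation itself rests on the names of the deposited arrays. Dye bias left over from the exchange is argued against because the median of all 74 measured members of these 4 lists was below 0 on every array, from -0.37 to -0.22, with an SD over cultures of at most 0.038 within a dye orientation. A loss of stromal, pericyte or smooth muscle cells stays open: the theca and stroma list was called lower (camera adjusted p = 0.0386; adjusted p = 0.404 with an estimated correlation), and of the markers of these cells, some shared with the mesenchymal list, 2 were higher and 5 lower, and at 2-fold or more 1 was higher (Pdgfrb, 2.50) and 2 lower (Ogn, -2.05, and Acta2, -1.19). A change in the cells themselves is a hypothesis that was not tested against this loss. The dimmer probes of Col1a2, Ccn2 and Cdh11, which did not show the fall, limit it. Serum concentration and phenotype changed together in every culture, so they cannot be told apart as the source of these changes either.

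The hypoxia and unfolded protein response lists were both called lower at camera's preset correlation, and neither with an estimated one (adjusted p = 0.324 for both). Leftover dye bias is argued against as the whole source, since the median of all 36 measured members was below 0 on every array, from -0.59 to -0.11, with an SD over cultures of at most 0.075 within an orientation. The median lay nearer 0 on every array with mesenchymal RNA in Cy3, and over all 6 arrays the SD was 0.18. Serum concentration and phenotype cannot be told apart as the source, since they changed together in every culture; the median over all members of both lists was -0.17.

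Probes of the same gene could disagree. Among 718 pairs in 531 genes with a called probe, 47 pairs in 38 genes differed by 2-fold or more. Signal near the negative controls is argued against as the source of most of them, with 2.13% of the less changed probes at that level against 0.894% in the other pairs, and so is saturation of the less changed probe, at 8.51% against 3.73%. The less changed probe was the dimmer in 53.2% of these pairs and in 68.0% of the others. Misassigned clones and transcript variants were not tested.

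The assignments of the 2 parts of each culture to the 2 sides number 4, too few for a share under 0.05. The real assignment called 2088 genes with limma, the only 1 of the 4 to call as many, and the highest of the others called 0, with 90 to 1184 genes at an unadjusted p under 0.05 against 4158. Turning 1 culture moves any change that the cultures share into the spread between them. Few calls then follow from the construction, and no conclusion is drawn from them.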
